A study of Mus musculus with 6 samples.

How the data were processed

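The data are gene-level RNA-seq values of F4/80+ cells from orthotopic Hepa 1-6 liver tumours in mice, 3 libraries from control tumours and 3 from tumours of Sms-overexpressing cells, taken 14 days after injection. Per the labels' protocols, libraries were made from total RNA by selection on oligo(dT) beads, fragmentation, and second-strand synthesis with dUTP followed by digestion with UDG, which marks the strand. Per the submitters' processing notes, the tools were cutadapt 1.9, FastQC 0.11.9, HISAT2 2.2.1, StringTie 2.1.6 and DESeq2. The genome build, the annotation and the strand setting used for counting are not given in the sources used here. Reads of overlapping antisense genes could not be told apart with certainty.

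The deposited table holds estimated counts per gene, not normalized, as whole numbers. More genes held the value 4 than 3, 2 or 5 in every library (1008 against 580, 741 and 352 in control replicate 1), an excess that can arise when coverage is converted to counts. How the counts were made is not given, so their counting error is uncertain. The tests treated the values as counts and also used the spread between replicates. Totals were 49833764 to 58154006 per library, so 1 CPM stands for about 50 counts or more. Of 55401 rows, 25690 were 0 in every library. Gene symbols came from GENCODE M21 by Ensembl identifier, for 55141 rows; the other 260 rows held at most 0.0125% of a library's counts. Coordinates are those of GENCODE M21 on GRCm38, matched by identifier. Counts of near-identical genes (the Saa, Serpina1, Serpina3, Mup, Ear and globin families, Hspa1a and Hspa1b, and nuclear copies of mitochondrial genes such as that of mt-Co2) are uncertain, since reads could be split among copies.

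Groups and replicate numbers came from the sample titles, and table columns were matched by the sample descriptions. All 6 were used as separate samples, as the titles list them. No 2 libraries of 1 group held the same values: at most 17.3% of genes with a count in any library had identical counts. Labels name no batch.

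Before the data were examined, the test, the gene lists, the cell type markers, the named-gene rule and most alternatives were fixed. The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM factors, robust glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over the 18277 genes kept and a threshold of 0.05. Log2 fold changes are Sms_OE minus control as edgeR fits them, with a prior count of 0.125, and standard errors were derived from the F statistic. CPM use library sizes scaled by TMM factors, and composition used totals of all rows. Lists with at least 5 tested members, 41 of 42, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists, and repeated with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether its own genes move. With an estimated correlation in camera 0 lists passed (smallest adjusted p 0.301; 4 lists at an unadjusted p under 0.05, the smallest 0.0161), and fry called 18. Library measures (23 of them) and the M2 minus M1 difference, on log2 CPM with a prior count of 2, were compared by two-sided exact permutation over 20 assignments.

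Named genes were Sms, 10 readouts, and the 12 largest rises and falls past the threshold with a mean CPM of at least 5, non-overlapping groups and an ordinary symbol. For each list they were up to 4 members past the threshold by smallest p, or the 2 of highest CPM where none passed. Where genes outside this rule are named, the text says that they were chosen after their values were seen.

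The steps were tested on simulated counts for the Sms_OE against control comparison, drawn from the real means, depths and dispersions with 200 genes changed, of 17708 genes tested. Of those changed by a log2 fold of 0.5, 1 and 2, the test recovered 20.9%, 71.6% and 93.9%, and 7.46% of its calls were unchanged genes. When 1 of the 41 lists was lowered by a log2 fold of 0.5, camera called it and 2 others. Far fewer genes were changed than passed the threshold in the data, and genes were drawn independently, so these rates need not hold there.

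Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors and library size alone; no low-count filter or a CPM of at least 1 in 3 libraries; the DESeq2 Wald test and limma-voom with quality weights; no robust step, the replicate number as a block and named rows only. Others were the mean log2 CPM of hepatocyte and hepatoma markers as a covariate, each library left out and other thresholds. Added after seeing the data were per-library offsets for gene length and GC, removal of mitochondrial and haemoglobin rows, and removal of both haemoglobin-rich libraries. Transcript length and GC were those of the longest GENCODE M21 transcript, known for 99.9% of tested genes. Offsets were fitted on genes above a mean log2 CPM of 2. In a further comparison, also added after seeing the data, list members above that level were set against the 100 genes nearest in length and GC. No file or column was left out.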

Results

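RNA was measured in F4/80+ cells, the surface marker used here to isolate macrophages, taken from mouse liver tumours 14 days after Hepa 1-6 cells, a mouse hepatoma line, had been injected into the liver. In 3 libraries the injected cells were controls, and in 3 they overexpressed Sms, the gene of spermine synthase, which makes the polyamine spermine. The control libraries held 58154006, 57278063 and 51583985 estimated counts, and the Sms_OE libraries 50050172, 51123047 and 49833764. Between 22713 and 23699 of the 55401 listed genes had at least 1 count in a library. The labels call the samples replicates and do not say whether each came from its own mouse, so p-values measure the spread between these samples. The series title names M2 polarization of macrophages. The design gives 1 comparison, F4/80+ cells from Sms_OE tumours against F4/80+ cells from control tumours.

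Sms itself, which by the labels was overexpressed in the tumour cells and not in the sorted cells, stood at 26.9 ± 1.3 CPM in the controls and 33.1 ± 0.15 CPM in Sms_OE (mean ± SD, n = 3 each). The gene (ENSMUSG00000071708) lies on chromosome X, 157443855 to 157492287, in GRCm38. Its log2 fold change was 0.30 ± 0.094 (SE), a 1.23-fold difference, with an adjusted p of 0.0382 by edgeR's quasi-likelihood test, and every Sms_OE value lay above every control value. The call was lost whenever any 1 of the 6 libraries was left out, with adjusted p between 0.0719 and 0.122. Sms in the injected cells themselves was not measured in these data.

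Expression differed widely between the groups: 4908 of 18277 tested genes passed the threshold of an adjusted p under 0.05, 2293 of them higher and 2615 lower in Sms_OE. Of these, 1131 changed by a log2 fold change of at least 1, 653 upward and 478 downward. The genes with the largest rises were Iqcn, from 0.917 ± 0.26 to 15.1 ± 5.0 CPM, Gja1, the gap junction protein connexin 43, from 1.65 ± 0.75 to 21.6 ± 1.7 CPM, and Ptges, which makes prostaglandin E2, from 5.80 ± 1.1 to 43.3 ± 18 CPM (mean ± SD, n = 3). Their log2 fold changes were 4.04 ± 0.30, 3.69 ± 0.29 and 2.90 ± 0.29 (SE), with adjusted p of 8.9e-05, 0.00013 and 0.00055. Csf3, the growth factor G-CSF, rose 6.21-fold, Pdpn 6.58-fold, Apol8 7.21-fold and Cacna1d, a calcium channel subunit, 6.67-fold. Phc3, a Polycomb group protein, had the smallest p among the rises, at 4.81-fold (log2 2.27 ± 0.11, adjusted p = 1.3e-05). The 12 largest falls were, except for Rhox5, genes of plasma proteins made by the liver, described with the hepatocyte markers. With library size alone as the scaling, 2521 genes were higher and 1788 lower, so the split between the directions depends on the scaling. The counts also fell without control replicate 2, to 3050 genes, 1366 higher and 1684 lower, and without control replicate 3 the number of higher genes was 1498.

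**Figure D1:**
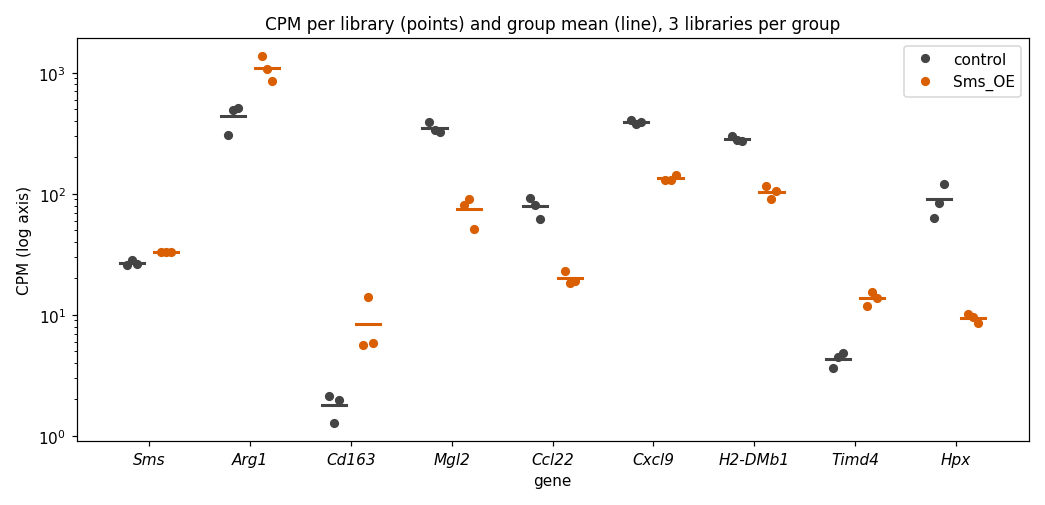
CPM of 9 genes on a log axis, with a point for each library and a line at the mean of each group of 3. All 3 Sms_OE points lie above the controls for Sms, Arg1, Cd163 and Timd4 and below them for Mgl2, Ccl22, Cxcl9, H2-DMb1 and Hpx.

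Genes used as marks of alternative (M2) activation moved in both directions. Arg1, arginase 1, which turns arginine into ornithine, rose 2.52-fold, from 437 ± 114 to 1101 ± 261 CPM (log2 1.33 ± 0.22 SE, adjusted p = 0.00347), and Cd163, a haemoglobin scavenger receptor, rose 4.72-fold at a low level, from 1.80 ± 0.44 to 8.48 ± 4.8 CPM (adjusted p = 0.0026). Other members of the list fell. Mgl2, a C-type lectin, fell 4.73-fold (352 ± 33 to 74.4 ± 21 CPM, log2 -2.24 ± 0.19). The chemokines Ccl22 and Ccl24 fell 3.91-fold (log2 -1.97 ± 0.15) and 3.98-fold (log2 -1.99 ± 0.20), and the lectin Clec10a 2.49-fold (log2 -1.31 ± 0.12). The adjusted p of these genes were 0.00019, 0.00012, 0.00037 and 0.00021. Mrc1, the mannose receptor CD206, gave -0.09 ± 0.20 and Chil3 -0.07 ± 0.77, and neither passed the test. Of 25 list members tested, 5 rose, 9 fell and 11 did not pass, and adjusted over the list alone 7 rose and 10 fell. The list was called lower by camera with a preset correlation (adjusted p = 0.0197, median log2 fold change -0.09, mean -0.26), and not with an estimated correlation (adjusted p = 0.466). Without Sms_OE replicate 3 the median was 0.02 while the test still placed the list lower, and without Sms_OE replicate 1 the adjusted p was 0.0598. With offsets for gene length and GC, chosen after seeing the data, the median was 0.02 (adjusted p = 0.0651).

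Genes of classical (M1) activation were also divided. Cxcl9, a chemokine induced by interferon-gamma, fell 2.92-fold, from 392 ± 13 to 134 ± 8.4 CPM (log2 -1.54 ± 0.09, adjusted p = 4.2e-05), and the costimulatory receptor Cd40 fell 2.23-fold (log2 -1.16 ± 0.10, adjusted p = 0.00014). Il12a, a subunit of interleukin 12, rose 4.63-fold at a low level (1.23 ± 0.28 to 5.71 ± 1.9 CPM), Cd38 rose 1.73-fold, and Nos2, inducible nitric oxide synthase, rose 1.88-fold (69.9 ± 18 to 132 ± 39 CPM, adjusted p = 0.031). The Nos2 call was lost without control replicate 1 (adjusted p = 0.0502) and without control replicate 3 (adjusted p = 0.0796). Cd80, Cd86 and Cd274 (PD-L1), with log2 fold changes of 0.28 ± 0.14, -0.31 ± 0.12 and 0.06 ± 0.11, did not pass. Of 26 members 6 rose, 9 fell and 11 did not pass (7 and 12 adjusted over the list alone), and the list missed the threshold (adjusted p = 0.0666, median -0.27, mean -0.15). Without control replicate 1 its adjusted p was 0.0235. The mean log2 CPM of the M2 list minus that of the M1 list was 0.24 ± 0.04 in the controls and 0.11 ± 0.23 in Sms_OE (SD, n = 3). The difference of -0.13 did not exceed the spread between replicates (two-sided exact permutation test, p = 0.7, where 0.1 is the smallest p that 3 against 3 can give). Without Sms_OE replicate 3 the difference was -0.0012.

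**Figure D2:**
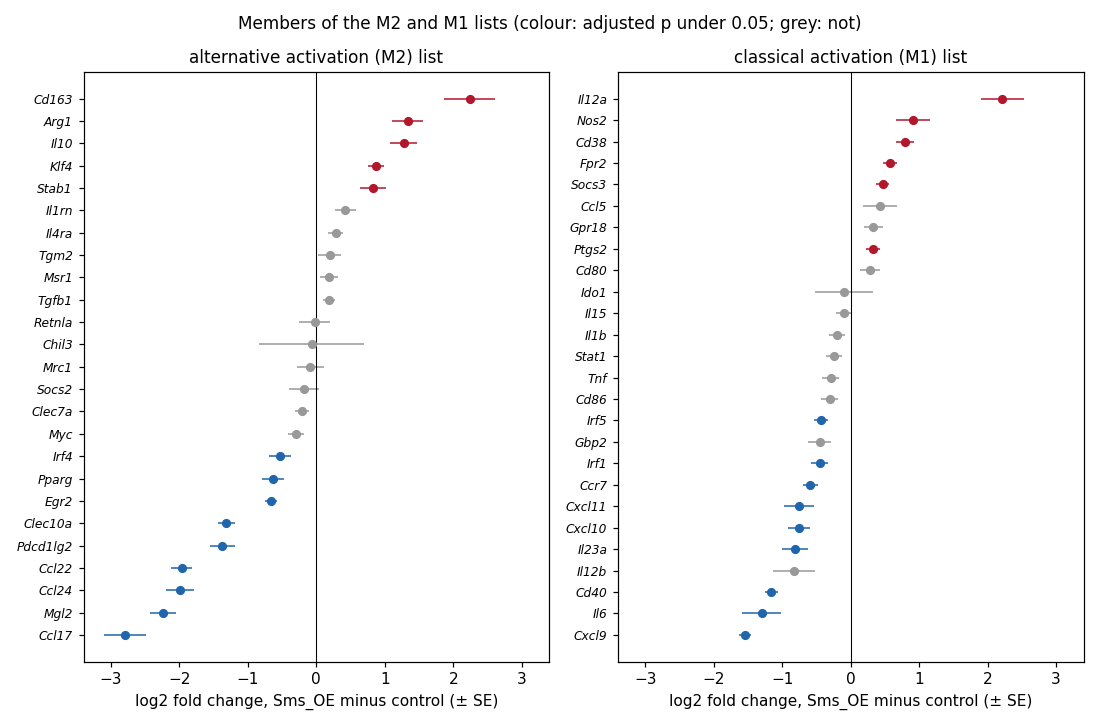
Log2 fold change (Sms_OE minus control) of each tested member of the M2 list (left, 25 genes) and the M1 list (right, 26 genes), with bars of 1 standard error. Coloured points passed an adjusted p of 0.05, and grey points did not; in both lists members lie on both sides of 0, from Ccl17 at -2.79 to Cd163 at 2.24.

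RNA of genes for antigen presentation by MHC class II was lower in Sms_OE. Of 12 members tested, 11 fell and none rose (12 fell adjusted over the list alone), with a median log2 fold change of -1.07 (camera adjusted p = 2.78e-18 with a preset and adjusted p = 0.301 with an estimated correlation). H2-DMb1 and H2-DMa, which load peptides onto class II molecules, fell 2.73-fold and 2.32-fold, H2-DMb2 3.36-fold, and Ciita, the transcriptional activator of class II genes, 2.35-fold (162 ± 30 to 68.8 ± 6.0 CPM, log2 -1.23 ± 0.13, adjusted p = 0.00033). Dendritic cell markers were lower in the same comparison (5 of 15, with 2 higher, or 4 and none without control replicate 2, median -0.34, adjusted p = 0.00342, and adjusted p = 0.403 with an estimated correlation). The interferon-gamma list had 10 members lower and none higher of 23 (12 adjusted over the list alone, median -0.39, adjusted p = 1.42e-07, and adjusted p = 0.466 with an estimated correlation). Among them the GTPase Iigp1 was 1.96-fold and the immunoproteasome subunit Psmb9 1.68-fold lower. Ifng, the gene of interferon-gamma, was 1.77-fold higher (12.1 ± 2.2 to 21.4 ± 2.6 CPM, adjusted p = 0.0051). The MHC class I list had 6 of 18 members lower and none higher (6 adjusted over the list alone, median -0.12, adjusted p = 0.0462, adjusted p = 0.703 with an estimated correlation, and adjusted p = 0.138 by fry). Psmb8 was 1.56-fold lower. The type I interferon list had 6 of 27 lower and none higher (5 adjusted over the list alone, adjusted p = 0.0107, adjusted p = 0.703 with an estimated correlation, and adjusted p = 0.228 by fry), led by Oas1a at 1.53-fold lower. Without Sms_OE replicate 1 its adjusted p was 0.206, and with the length and GC offsets 0.096. Its number of lower members depended on single libraries, 2 without control replicate 1 or Sms_OE replicate 1 and 14 without Sms_OE replicate 3. Without 1 library, the class I call was lost without control replicate 2, control replicate 3 or Sms_OE replicate 1 (adjusted p between 0.0599 and 0.302), and with the 3 other scalings (adjusted p between 0.0595 and 0.0778).

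Chemokine genes fell more often than they rose: 10 of 24 fell and 4 rose (11 and 6 adjusted over the list alone; median -0.40, adjusted p = 0.00203, and adjusted p = 0.466 with an estimated correlation). Ccl17, which attracts T helper 2 and regulatory T cells, fell 6.94-fold, from 57.6 ± 1.5 to 8.31 ± 4.0 CPM (log2 -2.79 ± 0.30, adjusted p = 0.00093). The call on the chemokine list was lost with limma-voom (adjusted p = 0.0744) and with the length and GC offsets (adjusted p = 0.0714). In the list of NF-kB targets and inflammasome genes 3 of 22 rose and 3 fell (3 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.734). Nlrp3, the inflammasome sensor, rose 1.72-fold and Cd83 fell 2.43-fold. On leaving out control replicate 2, no chemokine was higher and 8 were lower, and the NF-kB list gave 2 higher and 1 lower.

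Markers of Kupffer cells, the resident macrophages of the liver, were higher in Sms_OE. Of 16 tested members 10 rose and 2 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.85 (adjusted p = 3.42e-05, and adjusted p = 0.363 with an estimated correlation). Timd4, a phosphatidylserine receptor, rose 3.16-fold (4.32 ± 0.59 to 13.7 ± 1.9 CPM, log2 1.66 ± 0.18, adjusted p = 0.00033), and Fcna and Id3 rose 2.11-fold and 1.88-fold. Clec4f, a lectin restricted to Kupffer cells, named here after its values were seen, rose by a log2 fold change of 1.86 ± 0.26 (24.9 to 90.1 CPM). Clec4g, a lectin of sinusoidal endothelial cells that is also on the list, named after its values were seen as well, had the list's lowest log2 fold change, -2.20 ± 0.47 (8.82 ± 1.7 to 1.92 ± 1.4 CPM, adjusted p = 0.0102). Nr1h3, the oxysterol receptor LXR-alpha, fell 1.77-fold. The list of C1q and tissue-resident macrophage genes split into 5 higher and 7 lower of 18 (5 and 8 adjusted over the list alone, adjusted p = 0.708). F13a1 rose 3.45-fold (30.0 ± 5.0 to 104 ± 14 CPM), and C1qb and Ccl12 were 1.58-fold and 2.86-fold lower. The lipid-associated macrophage list also split, 5 higher and 6 lower of 20 (5 and 9 adjusted over the list alone, adjusted p = 0.708). Abca1, which exports cholesterol, rose 3.30-fold (57.1 ± 5.3 to 189 ± 19 CPM, log2 1.72 ± 0.11, adjusted p = 4.8e-05), and Ctsl rose 2.01-fold. Plin2, which coats lipid droplets, rose by a log2 fold change of 0.59 ± 0.087 (SE), and lipoprotein lipase, Lpl, fell 3.28-fold (371 ± 47 to 113 ± 12 CPM). Among inflammatory monocyte genes 4 of 15 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.139), with the chemokine receptor Ccr2 1.79-fold lower and fibronectin, Fn1, 2.36-fold higher (adjusted p = 0.0899 with the length and GC offsets). Without control replicate 1 the adjusted p of that list was 0.0309, and with no low-count filter 0.0317. Its lower members numbered 2 without control replicate 2 or 3. General macrophage markers gave 2 higher and 5 lower of 14 (3 and 5 adjusted over the list alone, adjusted p = 0.406). Adgre1, the gene of F4/80, and Csf1r gave 0.34 ± 0.17 and 0.17 ± 0.10 and did not pass, while Itgam (CD11b) rose 1.52-fold and Aif1 fell 1.89-fold.

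RNAs of the respiratory chain and the ribosome were lower. All 25 nuclear-encoded oxidative phosphorylation genes tested fell (25 adjusted over the list alone), by a median log2 fold change of -0.67 (adjusted p = 4.14e-20, and adjusted p = 0.301 with an estimated correlation), with Cox5a 1.97-fold and Ndufa9 1.88-fold lower. Of 37 mitochondrially encoded genes 28 fell and none rose (30 adjusted over the list alone, median -1.30, adjusted p = 1.78e-17, and adjusted p = 0.403 with an estimated correlation). mt-Nd4 fell 2.96-fold and mt-Cytb 3.21-fold, and the mitochondrial share of all counts was 5.97 ± 1.1% in the controls and 2.57 ± 0.50% in Sms_OE (SD, n = 3, two-sided exact permutation test, p = 0.1, the smallest possible). Of 87 ribosomal protein genes 73 fell and none rose (75 adjusted over the list alone, median -0.57, adjusted p = 6.87e-21, and adjusted p = 0.466 with an estimated correlation), with Rpl14 1.60-fold lower. With the length and GC offsets 27 of 87 ribosomal protein genes were lower (median -0.22), 14 of 37 mitochondrially encoded genes (median -0.59) and 18 of 25 oxidative phosphorylation genes (median -0.41). Several mitochondrial genes shared nearly identical counts with nuclear copies in the table, so their level is uncertain. Fold changes moved with transcript length across genes, which are not independent replicates: of 4 equal groups of genes by length, the shortest held 233 higher and 808 lower, and the longest 1198 higher and 331 lower.

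Cholesterol synthesis and cell cycle genes fell as well. Of 19 cholesterol synthesis genes 14 fell and none rose (14 adjusted over the list alone, median -0.60, adjusted p = 2.6e-06, and adjusted p = 0.466 with an estimated correlation). Fdps and Idi1 were 2.04-fold and 2.05-fold lower. Of 25 cell cycle genes 15 fell and 1 rose (18 and 1 adjusted over the list alone, median -0.64, adjusted p = 3.39e-07, adjusted p = 0.466 with an estimated correlation, and adjusted p = 0.0605 by fry). Rrm2, a subunit of ribonucleotide reductase, was 1.86-fold and the replication helicase subunit Mcm7 2.08-fold lower. In the list of fatty acid oxidation and cholesterol efflux 10 of 19 fell and 3 rose (12 and 4 adjusted over the list alone, median -0.40, adjusted p = 0.0462, and adjusted p = 0.466 with an estimated correlation). The electron carriers Etfa and Etfb were 1.57-fold and 1.59-fold lower. That call was lost without control replicate 1 (adjusted p = 0.0655) and without Sms_OE replicate 2 (adjusted p = 0.16), and with the 3 other scalings (adjusted p between 0.0595 and 0.082). Hypoxia genes gave 9 higher and 2 lower of 20 (10 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.0198, adjusted p = 0.581 with an estimated correlation, and adjusted p = 0.0873 by fry), with the glucose transporter Slc2a1 1.52-fold higher. That call too was lost without control replicate 1 (adjusted p = 0.0745) or Sms_OE replicate 2 (adjusted p = 0.096). On leaving out control replicate 2, hypoxia genes gave 3 higher and 1 lower, fatty acid oxidation and efflux 1 higher and 6 lower, and neither the higher cell cycle gene nor the lower glycolysis gene passed. The cholesterol list had 9 lower without control replicate 1. Glycolysis was not called (2 higher and 1 lower of 18, the same numbers adjusted over the list alone; median -0.12 and mean 0.01 while the test placed it higher, adjusted p = 0.708), although Pfkfb3, which drives glycolytic flux, rose 2.26-fold (98.1 ± 4.6 to 221 ± 17 CPM, adjusted p = 0.00012). Histone genes, chosen by symbol as replication-dependent genes whose transcripts lack poly(A) tails, gave 4 lower and none higher of 46 (4 adjusted over the list alone, adjusted p = 0.373). Hist1h1c was 1.86-fold lower. The symbols also took in H1f0, a replication-independent histone gene whose transcript has a poly(A) tail, which was among the 4 lower.

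Polyamine genes in the sorted cells changed in both directions, 7 higher and 6 lower of 24 (10 and 6 adjusted over the list alone, adjusted p = 0.316). Spermidine synthase, Srm, fell 1.92-fold (20.2 ± 3.0 to 10.5 ± 2.5 CPM, log2 -0.94 ± 0.18, adjusted p = 0.005), Mtap, which salvages the by-product of polyamine synthesis, fell 1.56-fold, and spermine oxidase, Smox, rose 1.45-fold (213 ± 3.4 to 308 ± 40 CPM). The polyamine counts were 3 and 3 without control replicate 2, and 2 and 5 without control replicate 3. Odc1, ornithine decarboxylase, named after its values were seen, gave -0.41 ± 0.10 (adjusted p = 0.016). Of 26 genes of the PI3K-Akt-mTOR pathway 7 were higher and 2 lower (7 and 3 adjusted over the list alone, adjusted p = 0.139, and adjusted p = 0.0395 by fry), with the adaptor Pik3ap1 1.64-fold, Rictor 1.52-fold and Pik3r5 1.40-fold higher. Without control replicate 2 the numbers of that pathway were 5 and 1. Among immune checkpoint and inhibitory receptor genes 6 of 23 were higher and 2 lower (6 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.0922). On leaving out control replicate 1 or 2, 5 were higher and 1 lower. The list passed with library size alone (adjusted p = 0.0493), by fry (adjusted p = 0.0424) and with the length and GC offsets (median 0.21, adjusted p = 0.0193). Nt5e (CD73), which makes adenosine, rose 3.00-fold (10.4 ± 1.7 to 31.1 ± 2.7 CPM, log2 1.59 ± 0.15, adjusted p = 0.00019). The TGF-beta receptor Tgfbr2 rose 1.63-fold, and Pdcd1lg2 (PD-L2) fell 2.59-fold (73.8 ± 1.9 to 28.5 ± 8.8 CPM).

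Immediate early and dissociation stress genes were higher, 11 of 24 with 2 lower (the same numbers adjusted over the list alone; median 0.27, adjusted p = 0.00126, and adjusted p = 0.466 with an estimated correlation). Fosb rose 1.96-fold (747 ± 65 to 1465 ± 135 CPM), the heat shock genes Hspa1a and Hspa1b, near-identical copies, 1.82-fold and 1.75-fold, and Egr2 fell 1.59-fold. The unfolded protein and integrated stress response list gave 5 higher and 8 lower of 20 (6 and 10 adjusted over the list alone, adjusted p = 0.266), and the chaperones and folding enzymes Sdf2l1, Pdia6 and Pdia4 were 1.98-fold, 1.66-fold and 1.59-fold lower. Lysosome and phagocytosis genes gave 3 higher and 9 lower of 26 (3 and 10 adjusted over the list alone, adjusted p = 0.224, and adjusted p = 0.0317 with no low-count filter), with Psap 1.78-fold lower. Angiogenesis and matrix genes gave 6 higher and 3 lower of 25 (6 and 3 adjusted over the list alone; median 0.04 and mean -0.01 while the test placed the list higher, adjusted p = 0.662), with the protease Plau 1.93-fold lower. Without control replicate 2 the stress response list gave 3 higher and 5 lower, the lysosome list 3 and 3, and the matrix list 3 and 1.

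Transcripts of other cells were present in all libraries. The neutrophil list summed to 9086 ± 824 CPM in the controls and 8726 ± 885 CPM in Sms_OE (SD, n = 3). The macrophage list summed to 8787 ± 323 and 9933 ± 803 CPM. Such sums depend on which genes a list holds, so they do not give the shares of cell types. Dendritic cell and T cell lists summed to 1374 and 618 CPM in the controls, and to 1253 and 871 CPM in Sms_OE. A gene's level here is therefore that of the sorted cells together, and not of macrophages alone. The list with the lowest median log2 fold change was that of hepatocyte markers: 18 of 22 fell and none rose (19 adjusted over the list alone), by a median log2 fold change of -3.22, or -3.16 with Cps1, which had 0 counts in all 3 Sms_OE libraries, set to its bound at a floor of 3 counts per library (adjusted p = 6.87e-21, and adjusted p = 0.301 with an estimated correlation). Their summed level went from 1072 ± 116 to 605 ± 124 CPM (SD, n = 3, two-sided exact permutation test, p = 0.1, the smallest possible), and the abundant Trf, named after its values were seen, gave 0.05 ± 0.13. Hpx, hemopexin, fell 9.51-fold (89.8 ± 30 to 9.43 ± 0.85 CPM, log2 -3.25 ± 0.23, adjusted p = 0.00014), Serpina3k 28.6-fold (57.1 ± 17 to 1.99 ± 0.12 CPM), Itih4 16.0-fold, and the fibrinogen chains Fga and Fgg 11.5-fold and 11.6-fold. The acute phase genes Saa1 and Saa2 fell 34.2-fold and 29.6-fold. These, Serpina3k and Serpina1d belong to families of near-identical genes whose counts could be shared. Alb, named after its values were seen, fell by a log2 fold change of 1.03 (SE 0.17). Hepatoma markers were not called (1 higher and 1 lower of 10, none higher and 1 lower adjusted over the list alone, median 0.10, mean -0.02, placed higher by the test, adjusted p = 0.953), with Gpc3 falling 2.52-fold. The 1 higher member, Sox9, lost its call without control replicate 2 or 3, or Sms_OE replicate 1 or 3 (adjusted p between 0.0968 and 0.126). Rhox5, a homeobox gene of the X chromosome, fell 13.9-fold (9.94 ± 1.3 to 0.712 ± 0.47 CPM). Endothelial markers fell, 11 of 18 with 1 higher (13 and 1 adjusted over the list alone, median -0.92, adjusted p = 1.59e-06, and adjusted p = 0.403 with an estimated correlation), Flt1 and Dnase1l3 by 2.91-fold and 2.30-fold. Without control replicate 1 the number lower was 6, and without control replicate 2 no endothelial marker was higher.

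Among immune cells, dendritic cell markers gave 5 lower and 2 higher of 15 (6 and 2 adjusted over the list alone, median -0.34, adjusted p = 0.00342, and adjusted p = 0.403 with an estimated correlation), with Kmo 2.84-fold, Batf3 2.52-fold and Clec9a 2.11-fold lower. Without control replicate 1 or 2, or Sms_OE replicate 2 or 3, 4 were lower and none higher. T cell markers were higher in 4 of 18 and lower in none (4 adjusted over the list alone, median 0.46, adjusted p = 0.00279, adjusted p = 0.703 with an estimated correlation, and adjusted p = 0.226 by fry), led by Cd28 at 1.77-fold. Icos, Cd4 and Cd5 lost their calls without control replicate 1 or 2, or Sms_OE replicate 1 or 3 (adjusted p between 0.064 and 0.154), while 13 members were higher without Sms_OE replicate 2. NK and cytotoxic markers gave 3 higher and none lower of 14 (3 adjusted over the list alone, median 0.12, adjusted p = 0.222), and 1 higher without control replicate 2. That list passed with the length and GC offsets (median 0.46, adjusted p = 0.00613) and without the haemoglobin-rich Sms_OE replicates 2 and 3, left out after seeing the data (median 0.28, adjusted p = 0.0328). Neutrophil markers gave 3 higher and none lower of 17 (3 adjusted over the list alone, adjusted p = 0.55), with Mpo 3.20-fold higher (3.87 ± 1.4 to 12.4 ± 1.8 CPM), and passed with the length and GC offsets (adjusted p = 0.0399). The offsets over-corrected short transcripts of less abundant genes (median from 0.11 to 0.53). List passes gained only with them therefore need not reflect the cells. The neutrophil count fell to 1 without control replicate 2, where Elane (adjusted p = 0.0539) and Mmp9 (adjusted p = 0.117) lost their calls. Mmp9 also lost its call without control replicate 3, Sms_OE replicate 1 or Sms_OE replicate 3 (adjusted p between 0.0877 and 0.144), and without Sms_OE replicate 2 the counts were 3 higher and 2 lower. Eosinophil, basophil and mast cell markers gave none higher and 1 lower of 15 (1 adjusted over the list alone, median 0.003, mean -0.07, placed lower by the test, adjusted p = 0.739). Ear2, whose family holds near-copies, fell 3.93-fold, a call lost without control replicate 1 (adjusted p = 0.0543). B and plasma cell markers gave 1 higher and none lower of 14 (none adjusted over the list alone, median 0.03, mean -0.01, placed lower by the test, adjusted p = 0.918). The 1, Igkc, passed in only 1 of the 6 fits without 1 library (adjusted p between 0.0825 and 0.166 in the others). Fibroblast and stellate markers gave 5 higher and none lower of 15 (5 adjusted over the list alone, adjusted p = 0.0626), with Dcn 1.88-fold higher, and cholangiocyte markers 3 higher and none lower of 9 (3 adjusted over the list alone, adjusted p = 0.139), with Spp1, also made by macrophages, 2.40-fold higher. The other 2 cholangiocyte genes, Sox9 and Krt19, lost their calls without control replicate 2 or 3, or Sms_OE replicate 1 or 3 (adjusted p between 0.0966 and 0.126), which left Spp1 alone. Krt19 also lost its call without Sms_OE replicate 2 (adjusted p = 0.0671). Of the fibroblast genes, Col1a2, Des and Col5a1 lost their calls without control replicate 2 or Sms_OE replicate 2 (adjusted p between 0.0549 and 0.112), where 1 of the 5 remained. Des and Col5a1 also did without control replicate 1 or 3 (adjusted p between 0.0537 and 0.0998), and Des without Sms_OE replicate 3 (adjusted p = 0.082). Tested as whole lists, both passed in some fits. Without Sms_OE replicate 3 the cholangiocyte list passed (adjusted p = 0.0109), as it did without both haemoglobin-rich libraries (adjusted p = 0.000915), and the fibroblast list passed with a CPM of at least 1 in 3 libraries (adjusted p = 0.0379) and by fry (adjusted p = 0.0398).

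Haemoglobin set individual libraries apart. The 4 globin genes summed to 44.1, 93.4 and 172 CPM in the control libraries, to 225 CPM in Sms_OE replicate 1, and to 4848 and 5124 CPM in Sms_OE replicates 2 and 3. The erythroid and platelet list was called higher (1 of 11 past the threshold, 1 adjusted over the list alone, adjusted p = 0.00573, adjusted p = 0.466 with an estimated correlation, and adjusted p = 0.0605 by fry). The 1 gene was Pf4 at 3.46-fold, against 9 genes without Sms_OE replicate 1. Pf4 is also on the list of C1q and tissue-resident macrophage genes, so its rise need not come from platelets. Without the mitochondrial and haemoglobin genes, an alternative chosen after seeing the data, the adjusted p of the list was 0.0514. With both of those libraries left out, an alternative chosen after seeing the data, 1384 genes passed, 690 higher and 694 lower, with 1 Sms_OE library assumed to vary like the controls. Of the sex-linked genes only Xist was tested, at 444 ± 17 CPM in the controls and 572 ± 24 CPM in Sms_OE (1.29-fold, adjusted p = 0.0143; without control replicate 2 or 3 the adjusted p was 0.0682 or 0.065). With the length and GC offsets its log2 fold change was -0.13 (adjusted p = 0.258).

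**Figure D3:**
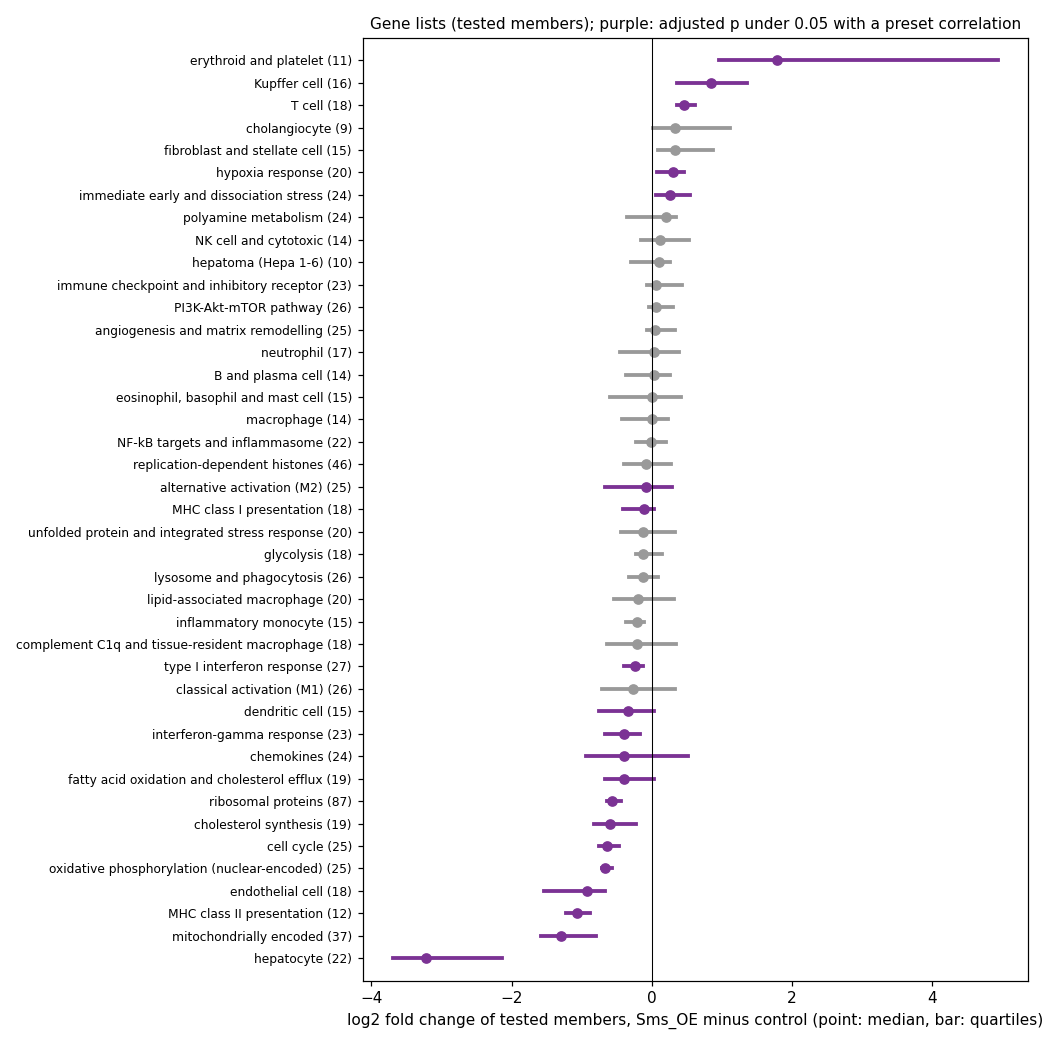
Median (point) and quartiles (bar) of the log2 fold changes, Sms_OE minus control, of the tested members of each of 41 lists, with the number of members in parentheses. Purple lists passed an adjusted p of 0.05 by camera with a preset correlation (20 lists, 5 higher and 15 lower); the hepatocyte list lies lowest at -3.22 and none passed with an estimated correlation.

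The libraries separated by group. The first principal component held 50.7% of the variance of the 500 most variable genes and placed the controls between -35.2 and -24.6 and Sms_OE between 23.4 and 32.6. Across genes, Pearson correlations of log2 CPM were 0.973 to 0.977 within the controls, 0.971 to 0.973 within Sms_OE and 0.948 to 0.961 between the groups. The 3 values of 1 group lay wholly above those of the other for 44.1% of tested genes, where chance gives 10%. The smallest p that an exact permutation of 3 against 3 libraries allows is 0.1, and no measure of library composition could pass 0.05 by it.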

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

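The fits with length and GC offsets, without mitochondrial and haemoglobin genes and without both haemoglobin-rich libraries were added after seeing the data. Under the other scalings, filters and tools and with named genes only, 4309 to 5613 genes passed the threshold. Of the 4908 genes of the standard analysis the DESeq2 Wald test shared 4893 and library size alone 4051, all in the same direction. With the length and GC offsets 3874 genes passed, 3021 of them shared and 3020 of these in the same direction. The log2 fold changes of single genes shifted by a median of 0.12, and the median over all genes went from -0.0006 to 0.07. The offsets removed the length trend among genes above a mean log2 CPM of 2 and over-corrected short transcripts below it, whose median went from 0.11 to 0.53. Requiring a log2 fold change of at least 1 left 1131 genes. Leaving out 1 library gave 3050 to 4488 genes, 1366 to 2015 higher and 1684 to 2473 lower. Without both haemoglobin-rich libraries 1384 passed, 690 higher and 694 lower, with fewer samples. Leaving aside the covariate fit and the fit without both haemoglobin-rich libraries, 134 of 167 named genes besides Sms kept their direction and side of the threshold. Named genes that had passed lost their calls in 33 cases without both of these libraries, in 13 with the length and GC offsets, in 4 with a replicate block and in 3 with library size alone. Leaving out 1 library cost 6 to 19 such calls, and using no low-count filter cost 5. Values that had not passed changed sign in some setting for 4 named genes and 15 lists.

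The replicate numbers did not pair the libraries: across genes, correlations of same-numbered deviations from group means lay between -0.01 and 0.06. With a replicate block 4532 genes passed (2117 higher, 2415 lower), Sms lost its call (0.30, adjusted p = 0.0596) and the M1 list gained 1 (-0.28, adjusted p = 0.0424).

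Sms also lost its call with no low-count filter (0.28, adjusted p = 0.0732), without both haemoglobin-rich libraries (0.29) and in each fit without 1 library (0.27 to 0.33). The M2 list lost its call with a CPM filter (-0.059), with limma-voom (-0.22) and with an estimated correlation (adjusted p = 0.466, median -0.088). Its median changed sign with the length and GC offsets (0.016), and lay between -0.30 and 0.016 without 1 library. The M1 list passed with no low-count filter (-0.29), by fry (-0.27) and without both haemoglobin-rich libraries (-0.35), and its median lay between -0.36 and -0.23 without 1 library. With an estimated correlation 0 lists passed in camera, against 20, with 4 at an unadjusted p under 0.05 and 18 called by fry. Calls lost by fry were those on type I interferon (adjusted p = 0.228), T cells (0.226), MHC class I (0.138) and hypoxia (0.0873). The cell cycle and the erythroid and platelet lists lost theirs too, each at an adjusted p of 0.0605 by fry. Xist (-0.13) and Ifitm6 (0.080) changed sign with the length and GC offsets. The M2 minus M1 difference kept its sign, from -0.22 to -0.0012 without 1 library. Except where stated, the cause was not tested.

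With the hepatocyte and hepatoma covariate 0 genes passed in edgeR, 0 higher and 0 lower, and 1121 had an unadjusted p under 0.05. The covariate separates the groups on its own (2.92 to 3.45 in the controls, 1.07 to 1.49 in Sms_OE), so group and covariate cannot be separated in that fit. The SE of Sms rose to 0.42 (log2 fold change 0.23), and the lists gave -0.24 for M2 and 0.19 for M1. Signs changed in that fit for Fgg (0.15), Ccl12 (0.99), Ifitm6 (0.57), Rictor (-0.034), Creld2 (0.15), Mmp14 (-0.42), Casp1 (0.055), Hspa1a (-0.13), Hspa1b (-0.11), mt-Nd4 (0.43), mt-Nd2 (0.58), mt-Cytb (0.57), mt-Nd4l (0.54), Rpl21 (0.14), Rpl10a (0.16), H1f0 (0.043) and Elane (-0.33). They also changed for Mmp9 (-0.38), Ear2 (0.12), Gpc3 (0.39), Sox9 (-2.12), Krt19 (-0.20), Des (-0.47) and Xist (-0.044). Lists that changed sign were lipid-associated macrophages (0.80), inflammatory monocytes (1.13), chemokines (1.12), mitochondrially encoded genes (0.55), ribosomal proteins (0.57) and hepatocytes (0.072).

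Depth limits genes of few counts, such as Mup3 in Sms_OE at 0.297 CPM.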

Other observations

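The tests of the cyclic AMP, NRF2 and glucocorticoid target lists, of nuclear-retained RNAs, of genes matched in length and GC, of dendritic cell, hepatoma and hepatocyte enzyme genes, and their criteria, were chosen only after the results were seen, as were the genes named in this part outside the naming rule. Of 17 genes that cyclic AMP and its transcription factor CREB induce, 12 were higher and none lower (median log2 fold change 0.61). Over the 5 lists added in this way the adjusted p by camera was 6.96e-11 with a preset correlation and 0.0851 with an estimated correlation. Nr4a3 rose by 1.55 ± 0.11 (SE), from 174 to 510.0 CPM, Fosb by 0.97 ± 0.11, Irs2 by 0.92 ± 0.12, Fosl2 by 0.89 ± 0.14 and the phosphodiesterase Pde4d by 0.78 ± 0.13, while Dusp1 gave -0.08 ± 0.10. Cyclic AMP itself was not measured, and Fosb, Nr4a1 and Dusp1 also belong to the immediate early and dissociation list, so a cyclic AMP signal and cell handling are both left open.

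The gene of the cystine transporter, Slc7a11, rose by 1.62 ± 0.16, from 297 to 910.1 CPM, and Txnrd1 by 0.89 ± 0.11, whereas Prdx1 fell by 0.71 ± 0.14. The list of NRF2 targets gave 5 higher and 2 lower of 16 (median 0.28, adjusted p = 0.0225 with a preset and adjusted p = 0.423 with an estimated correlation), which decides neither for nor against NRF2 activity. Glucocorticoid targets gave 10 higher and 1 lower of 17 (median 0.35, adjusted p = 0.000627 with a preset and adjusted p = 0.0996 with an estimated correlation). Cd163, F13a1, Sgk1 and Per1 were higher, while Fkbp5 and Tsc22d3 lay at -0.28 ± 0.13 and -0.26 ± 0.09 and did not pass the test, so glucocorticoid exposure is left open.

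Lower RNA of the respiratory chain and ribosome went with a length trend: among genes above a mean log2 CPM of 2, the median log2 fold change was -0.37 in the shortest of 4 groups of transcripts and 0.17 in the longest. Offsets for length and GC in each library brought these to -0.01 and -0.02 but moved the shortest of the less abundant genes from 0.11 to 0.53, an over-correction. They left oxidative phosphorylation genes at -0.48, ribosomal proteins at -0.29 and mitochondrially encoded genes at -0.66 relative to all genes. The median of all genes with the offsets was 0.07, above the -0.01 and -0.02 of these more abundant groups. Oxidative phosphorylation and ribosomal protein genes therefore lay less far below genes above a mean log2 CPM of 2. Against the 100 genes nearest in length and GC above that level, oxidative phosphorylation genes lay at -0.39 (quartiles -0.58 and -0.26, 25 of 25 below). The 13 mitochondrially encoded mRNAs lay at -1.09 (quartiles -1.31 and -0.94, 13 of 13 below). Ribosomal proteins lay at -0.23 (quartiles -0.33 and -0.13, 77 of 83 below). These values argue against the length or GC of the longest annotated transcript as the whole cause. The transcript expressed can be shorter, and matching on the longest would then leave part of a length effect in place. The matched genes of ribosomal proteins lay at -0.35 themselves, so a part stays open there; of the whole mitochondrially encoded list 17 of the 19 members abundant enough to compare lay below their matches (median difference -0.998, quartiles -1.15 and -0.74), and for the rest of its 37 members, which were not compared, length bias cannot be told apart from a change in the cells. Nuclear-retained RNAs had a median of 0.29 over 10 genes, of which 2 passed, both higher: Tug1 at 0.45 ± 0.09 and Xist at 0.36 ± 0.09. Malat1 at 0.44 ± 0.15 and Neat1 at -0.34 ± 0.14 did not pass. Camera with a preset correlation did not call the list (adjusted p = 0.103). With the length and GC offsets its median was 0.19, and camera placed it lower (unadjusted p = 0.806). The median without offsets lay between the criteria for and against a loss of cytoplasmic RNA, so that loss cannot be told apart either. A difference between macrophages of the 2 kinds of tumour was not tested.

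MHC class II genes lay at -0.89 relative to all genes with the same offsets (9 of 12 still lower). Against genes matched in length and GC they lay at -0.79 (12 of 12 below). These values argue against length or GC as the whole cause, with the same limit that lengths were those of the longest annotated transcript. Fewer dendritic cells in the F4/80 sort could lower them. Dendritic cell markers had a median of -0.34 with an SD of 0.73, against -1.07 for class II, a gap of 0.74 that about equals that spread, with Batf3, Kmo and Clec9a lower, so fewer dendritic cells cannot be told apart from lower class II expression per macrophage. Lower class II, Ccl17 and Mgl2 beside higher Kupffer markers may reflect another mix of macrophages, or of macrophages and dendritic cells, in the Sms_OE sorts. Bulk RNA leaves this open, also for the other lower members of the M2 list.

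Against fewer hepatoma cells as the source of the fall in hepatocyte RNA, the hepatoma list had a median of 0.10 over its 10 tested genes. Its abundant genes Afp, Krt18 and Krt8 lay at -0.13 ± 0.14, 0.23 ± 0.13 and 0.26 ± 0.18. However, bile duct cells also express Krt8 and Krt18, and Gpc3 fell (-1.33 ± 0.30, the lowest of the list). Rhox5, which is not on the list, fell as well. These values bear on the number of hepatoma cells only. Lower expression of liver genes in each Sms_OE hepatoma cell was not tested. Enzymes and urinary proteins of hepatocytes were lower in 6 of 9 tested genes. These were the enzymes Cyp2e1 (3.42 to 0.349 CPM), Cyp3a11, Cyp2c29 and Cps1, and the secreted urinary proteins Mup3 (4.76 to 0.297 CPM) and Mup20. Tat, Pck1 and the most abundant of the 9, Ass1, did not pass, at -0.74 ± 0.47, 0.59 ± 0.56 and -0.34 ± 0.12, and all 9 belong to the fixed hepatocyte list, so they are no independent evidence. Less RNA from host hepatocytes in the Sms_OE sorts is a candidate explanation, which F4/80 selection should limit in both groups. Alb stayed at 193 CPM in Sms_OE, which hepatoma cells could supply.

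The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4908 genes, 2293 higher and 2615 lower, and the highest of the other splits 0 in all 3 counts by edgeR, with up to 522 genes at an unadjusted p under 0.05; 1 split, the real one, gave as many. For lists the real split gave 20 and the highest other 14, so camera with a preset correlation also called lists in splits that mix the groups. Every other split put libraries of both groups on each side. The group difference then widened the spread within sides, so few gene calls could arise there. The uneven mix also kept part of that difference between the sides, so the 14 lists are no count of false calls.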
